A study of Mus musculus with 64 samples.

How the data were processed

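Total RNA from mouse (Mus musculus) eggs and preimplantation embryos was measured on 64 arrays of 2 colours, each hybridised with embryo RNA in the first channel and a common reference in the second. Per the labels, 28 arrays form a stage set with a second channel named Universal Control: unfertilized eggs, fertilized eggs, 2-cell, 4-cell and 8-cell embryos, morulae and blastocysts, 4 arrays each. The other 36 arrays form a treatment set with a second channel named Universal Reference and hold 12 groups of 3: control embryos at 21 h (early 1-cell), 32 h (late 1-cell), 43 h (early 2-cell) and 54 h (late 2-cell), and embryos with AM at 32, 43 and 54 h, AC and DMSO at 32 and 43 h, and CHX at 43 h. The labels do not spell out the abbreviations and do not say from when the hours count. They are read here, from knowledge of such studies and not from the labels, as α-amanitin, an inhibitor of RNA polymerase II, aphidicolin, an inhibitor of DNA polymerase, and cycloheximide, an inhibitor of translation, with dimethyl sulfoxide as the solvent. No label names doses. Groups and replicate numbers were taken from the labels alone.

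The authors deposited 1 table of processed values for 22575 probes, and no scanner output was used here. The deposited values behave as log10 ratios of the 2 channels: they lie between -2 and 2, so that ratios beyond 100-fold are held at a limit, with 1.47% of values at a limit and 1.12% at exactly 0. The log base is not named in the labels and was read from these limits. The background correction, the normalization within each array and the dye of each channel are not given in the sources used here. Values were multiplied by 3.32 to reach a log2 scale and turned in sign, so that a positive value means more RNA in the embryo than in the reference. Where all arrays of a group sat at the limit, a fold is given as a lower bound.

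That direction is likely, not settled. Its basis was a pair of gene lists. Of 9 probes for 8 oocyte genes, 8 were above the reference in unfertilized eggs and 9 were higher in unfertilized eggs than in blastocysts. Of 9 probes for 6 trophectoderm genes, 7 were higher in blastocysts. If the deposited sign ran the other way, every rise and fall given here would swap. All arrays ran the same way, since the lowest correlation between any pair of arrays across all probes was 0.503.

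Array medians on the log2 scale, in the order of the replicate numbers, were 0.10, 0.16, 0.20 and 0.24 for unfertilized eggs, 0.12, 0.07, 0.13 and 0.12 for fertilized eggs, 0.04, 0.00, 0.03 and 0.12 for 2-cell embryos and 0.09, 0.04, 0.06 and 0.06 for 4-cell embryos. They were 0.08, 0.13, 0.10 and 0.12 for 8-cell embryos, 0.07, 0.06, 0.07 and 0.10 for morulae and 0.07, 0.06, 0.07 and 0.07 for blastocysts. In the treatment set the medians were -0.02, 0.08 and 0.03 for 21 h controls, 0.05, 0.12 and 0.05 for 32 h controls, -0.35, 0.03 and 0.04 for 43 h controls and 0.01, 0.00 and 0.00 for 54 h controls. They were 0.15, 0.09 and 0.06 for AM at 32 h, 0.06, 0.08 and 0.04 at 43 h and 0.07, 0.00 and -0.00 at 54 h. For AC they were 0.11, 0.05 and 0.10 at 32 h and 0.11, 0.04 and 0.01 at 43 h, for DMSO 0.18, 0.06 and 0.04 at 32 h and 0.00, 0.00 and 0.00 at 43 h, and for CHX 0.00, 0.00 and 0.02.

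A fixed rule kept the values as deposited where the medians of a set lay within 0.5 log2 units of each other and quantile-normalized them otherwise. The stage set, with a span of 0.24, was kept as deposited. The treatment set, with a span of 0.53 owed to the first 43 h control array, was quantile-normalized. As deposited, the median difference over all probes was 0.18 for AM against control at 43 h, 0.20 for CHX, 0.17 for DMSO at 43 h, 0.20 for the controls from 43 to 54 h and -0.08 from 32 to 43 h. After quantile normalization it was 0.03, 0.07, 0.01, 0.04 and 0.05, and changes are reported relative to those medians.

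Probes were named through the platform annotation supplied with the table: 4262 probes carry 1 gene symbol (3089 genes), 6822 carry several and 11491 are unnamed here. Of the 4262, 4247 were matched to current genes by Entrez number and 0 changed symbol. Probes with several symbols entered every test but were given no name. Control spots could not be told from other features by the annotation and were kept. For 867 genes with several probes, each probe was tested on its own, and a gene named in the text is given by its probe of largest difference unless the text says otherwise. Among 86 pairs of probes for 1 gene that both varied over the stage set, the median correlation was 0.91, against -0.05 for random pairs of varying probes.

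Differences were tested per probe with limma 3.58.1 (lmFit, contrasts and eBayes) in R 4.3.3, with 1 mean per group, all groups of a set sharing an estimate of the spread, and a two-sided Benjamini-Hochberg adjusted p under 0.05 over the 22575 probes of each comparison. The sets were fitted apart because their reference channels are named differently. Consecutive stages were compared, with limma's F test over all of them. Controls were compared between consecutive hours, AM, CHX and DMSO with the control of the same hour, AC with DMSO of the same hour, and CHX with AM at 43 h, and differences between effects were tested as contrasts. No label says whether the arrays of a group came from separate collections of embryos, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision, and no dye swaps are named. Beside counts of 0, the count at an unadjusted p under 0.05 is given. If no probe differed, a share of about 0.05 of the 22575 probes would still pass there. A count near or below that share is no sign of further changes.

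Of 26 gene lists, 22 had 5 or more measured genes and were tested with limma's camera, with a preset correlation between genes of 0.01 and, as an alternative, an estimated correlation. Each gene entered through its probe of highest mean value. Lists of cholesterol synthesis, p53 response, sperm, and blood and oviduct genes had 2, 3, 0 and 3 measured genes and were not tested. Beside a count of list members past the threshold over all probes, the count adjusted over the list alone is given. Genes were named by a fixed rule: the 8 largest rises and 8 largest falls per comparison among named probes past the threshold whose groups did not overlap, up to 4 members of each called list, and a short list of sentinel genes. Genes that the text takes from comparisons added later are said to be so.

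Probes at least 2-fold higher or lower in 2-cell embryos than in fertilized eggs in the stage set, 2197 and 2353 of them, are called 2-cell-activated and 2-cell-depleted, and were followed in the treatment set, which shares no array with it. Other settings tried were each array centred on its median, quantile normalization (or values as deposited), leaving out probes with a mean below the first quartile, fitting only the arrays compared, eBayes with trend and robust settings, the replicate number as a block, another control group, other set definitions and leaving out each array in turn. Leaving out probes at exactly 0, scaling each array to 1 interquartile range, an array batch as a block and fitting within a batch were added after the data were seen, as was leaving out arrays for the counts of 2-cell-activated and 2-cell-depleted probes and the correlation of the array sets. Apart from these additions and those named as such in the text, the groups, tests, scaling rule, gene lists, rule for named genes and settings were chosen before the data were examined.

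The steps were tested on simulated data made from the real probe means and spreads of the 22575 probes, with 200 probes changed. For 2-cell embryos against fertilized eggs, 28% of 100 probes changed by 1 log2 unit and 84% of 100 changed by 2 units were found, with 9 unchanged probes called. For AM against control at 54 h, 21% and 75% were found, with 7 unchanged probes called. The simulated noise was independent between probes and between arrays, with no batch and no array apart. The 200 changed probes were also far fewer than the probes called in the real comparisons. These rates therefore need not hold for the real arrays. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.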

Results

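The series followed RNA levels from the unfertilized mouse egg to the blastocyst in 28 arrays of 7 stages, and the response of 1-cell and 2-cell embryos to AM, AC and CHX in 36 arrays of 12 groups, each array read against a common reference. Values are log2 ratios of embryo to reference, and the direction of every difference is likely but not settled, on the basis of oocyte and trophectoderm genes. Btg4, an adapter for the decay of maternal mRNA, lay at 6.50 ± 0.29 (SD, n = 4) in unfertilized eggs and 2.10 ± 0.52 in blastocysts. The former is a lower bound, with 3 of the 4 arrays at the upper limit. The receptor Kit lay at 3.52 ± 0.81 and 0.33 ± 0.19, and the zona pellucida gene Zp2 at 3.22 ± 0.41 and 0.93 ± 0.34. Replicate arrays had mean correlations with the others of their group of 0.821 to 0.976 in the stage set and 0.760 to 0.972 in the treatment set. No pair of replicate arrays was a copy, the highest correlation between any 2 of them being 0.980.

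The stage arrays were divided into 2 parts that the labels do not name, called batches here although no label or header records one. The division was drawn from the splits and scores that follow, and not from a clustering of all 28 arrays. Unfertilized egg array 4 differed from eggs 1 to 3, and morula arrays 3 and 4 from morulae 1 and 2, in the same probes, with a correlation of 0.601 across probes between the 2 splits, which share no array. Fertilized egg 2 and 2-cell array 4 also stood apart. Their mean correlations with the rest of their groups were 0.850 and 0.821, against 0.838 for egg 4. Their deviations correlated with that of egg 4 at -0.131 and -0.130. On the axis from eggs 1 to 3 towards egg 4, all 8-cell and blastocyst arrays scored from 0.572 to 0.859, and all fertilized egg, 2-cell and 4-cell arrays from -0.646 to -0.185. The 17 arrays of the first batch had 322 to 372 features at the upper limit each, and the 11 of the second batch 69 to 312. The 8-cell embryos and blastocysts lie wholly in the second batch, and fertilized eggs, 2-cell and 4-cell embryos in the first. The number of probes called in each stage comparison is therefore also given with the batch as a block. Where a batch holds both stages, it is given within that batch too. For named genes such values are given for some only. Unfertilized eggs and morulae, which lie in both, are what makes the block possible, and the block takes out 1 shift per probe, equal at all stages. The batch split was noticed in the data and not planned. In the treatment set the third arrays of AM at 32 and 54 h and of AC and DMSO at 32 h had 93, 79, 5 and 156 features at the upper limit, against 298 or more in the other 32 arrays. Their deviations from the rest of their groups did not follow the egg axis, with correlations of -0.0631, -0.194, -0.01 and -0.000379 in a look added after the data were seen, and no batch was fitted there. The egg axis comes from the stage set and cannot exclude a technical run particular to the treatment set. Whether these arrays share such a run was not tested.

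**Figure D1:**
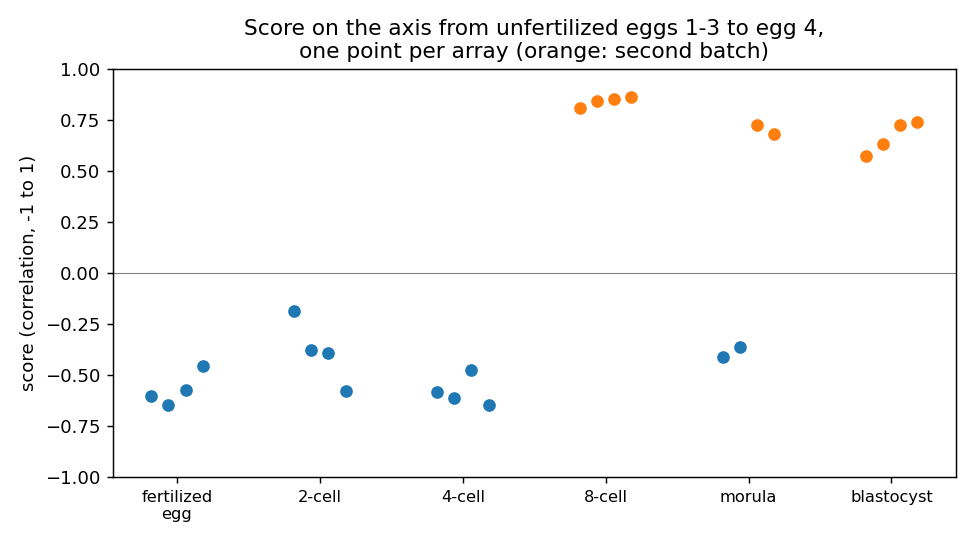
Score of each stage array (y axis, a correlation from -1 to 1) on the axis between unfertilized egg arrays 1 to 3 and array 4, by stage (x axis), with arrays of the second batch in orange and of the first in blue. The 8-cell and blastocyst arrays lie at 0.572 or higher and the fertilized egg, 2-cell and 4-cell arrays at -0.18 or lower, while morulae lie on both sides.

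RNA levels were compared over all stages: 14515 of 22575 differed between at least some stages by limma's F test, and 9242 with the batch as a block. Sycp2, a synaptonemal complex gene of meiosis, fell after fertilization, the lysosomal protease gene Ctsl rose to the 4-cell stage, and the chaperone gene Hspa8 rose from 2-cell to 4-cell embryos, as the per-array values show.

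**Figure D2:**
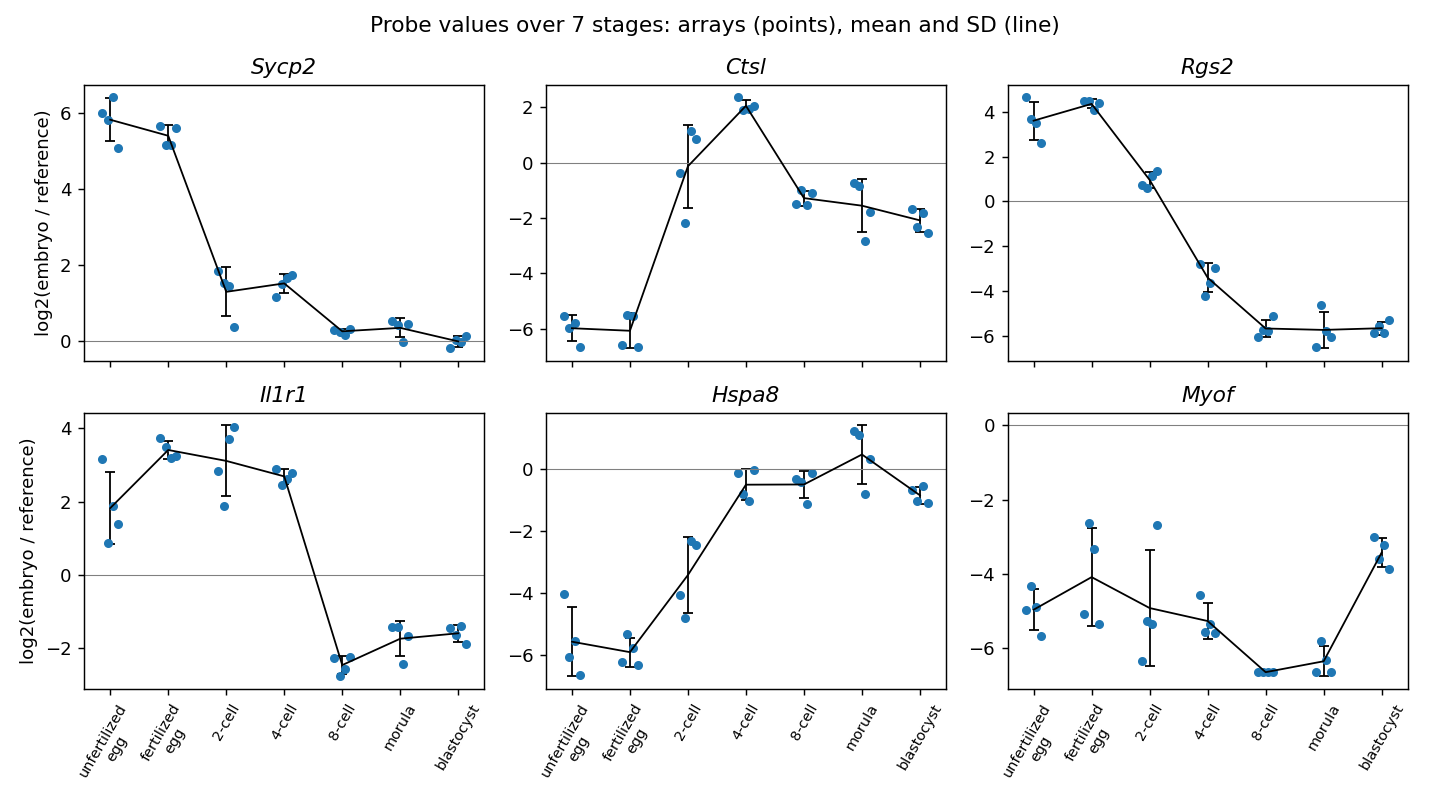
Log2 ratio of embryo to reference (y axis) over the 7 stages (x axis) for 1 probe each of Sycp2, Ctsl, Rgs2, Il1r1, Hspa8 and Myof. Points are arrays, 4 per stage, and the line joins stage means with SD bars. Sycp2 fell by 4.10 and Ctsl rose by 5.94 between the fertilized egg and the 2-cell embryo, the latter with 1 of 4 fertilized egg arrays at the lower limit.

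Fertilized eggs were compared with unfertilized eggs to see which transcripts change with fertilization. Slmap, which encodes a membrane-anchored protein, was 5.53-fold lower in fertilized eggs (log2 difference -2.47 ± 0.35 SE, n = 4 per stage, adjusted p = 0.00083). Transcripts of Saraf, a regulator of calcium entry, Lamb1, a laminin subunit, and Ptprf, a receptor phosphatase, were 5.26-fold, 5.30-fold and 3.85-fold lower, and Tmem59 was 4.76-fold lower. Rises were seen for Me1, the cytosolic malic enzyme (4.10-fold, log2 difference 2.04 ± 0.34), for the spindle gene Nusap1 (2.76-fold) and for the transcriptional regulators Arid5b and Id1 (2.24-fold and 2.22-fold).

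By limma 173 probes differed between unfertilized and fertilized eggs, 73 higher and 100 lower in fertilized eggs, and with each array centred on its median the split was 97 higher and 79 lower. With the batch as a block 374 probes differed (94 higher, 280 lower), 166 of the 173 among them. In a fit of the first batch alone, which lacks unfertilized egg 4, 288 differed (42 higher, 246 lower). Of the 8 largest named rises 8 passed with the block and 5 within the first batch, and of the 8 largest falls 8 passed in both. Within the first batch Saraf differed by -2.87, Lamb1 by -2.96 and Me1 by 1.61, all still past the threshold, while Nusap1 (1.43 ± 0.34 SE against 1.47 ± 0.28, adjusted p = 0.056) and Id1 (1.25 ± 0.32 against 1.15 ± 0.27, adjusted p = 0.087) were not. Their differences stayed about as large, with a wider SE from fewer arrays. The count rested on single arrays: it was 412, 371 and 379 without unfertilized egg 1, unfertilized egg 4 or fertilized egg 4, and 50, 21, 35 and 51 without unfertilized egg 2 or 3 or fertilized egg 2 or 3. In a fit of these 8 arrays alone limma called 0 probes, against 3513 at an unadjusted p under 0.05 in the fit of all stages.

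The step from fertilized egg to 2-cell embryo covers the replacement of maternal RNA by the embryo's own transcripts. Ctsl rose 61.5-fold (log2 difference 5.94 ± 0.51 SE, n = 4 per stage, adjusted p = 2.5e-09) and Clcn7, a lysosomal chloride transporter, 38.0-fold (5.25 ± 0.54). For Ctsl, Clcn7 and Hsph1 1 of the 4 fertilized egg arrays lay at the lower limit, and for Rbm26 1 of the 4 2-cell arrays, so that these folds are not exact. Hsph1, a chaperone of the heat shock family, rose 11.2-fold, Wipi2, which acts in autophagosome formation, 10.3-fold, Ankrd10 12.2-fold, Phactr1, a regulator of phosphatase and actin, 13.1-fold and Ccdc192 15.2-fold. Among transcripts that fell, Sycp2 was 17.2-fold lower (-4.10 ± 0.27), Fam13c 18.9-fold, the RNA-binding gene Rbm26 43.5-fold, the ubiquitin ligase subunit Fbxl5 14.2-fold and the membrane skeleton gene Epb41l5 13.0-fold, and the selenoprotein gene Selenos fell by 4.00 on the log2 scale. Btg4, at the upper limit in all 4 fertilized egg arrays, was at least 3.27-fold lower in 2-cell embryos (adjusted p = 0.011).

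Probes for 1 gene did not always move alike at this step. For Dnmt1, the maintenance DNA methyltransferase, probes 4902 and 17956 fell by 1.53 and 1.54 on the log2 scale and probe 15678 differed by -0.49 (adjusted p = 0.20). For Dnmt3b, a de novo methyltransferase, probe 1848 fell by 1.88, and probes 5582 and 5728 differed by -0.76 (adjusted p = 0.074) and -0.12 (adjusted p = 0.92). Cdkn1a, an inhibitor of cyclin-dependent kinases, rose 2.36-fold (adjusted p = 0.0039), with overlapping arrays.

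In all, 6183 probes differed by limma, 3276 higher and 2907 lower in 2-cell embryos, the counts at 2-fold or more being 2197 and 2353. In the blocked fit 7050 differed, and within the first batch, which holds all 8 arrays, 5517. All 7 rises and 6 falls of the largest size named here stayed past the threshold within it, the differences being the same by construction. No gene list was called, the lowest adjusted p being 0.15 for both ribosome biogenesis and translation factors (11 genes each), and with the mean of a gene's probes in place of 1 probe ribosome biogenesis was called higher (adjusted p = 0.037). The fit of these 8 arrays alone called 3218 probes.

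Between 2-cell and 4-cell embryos, some genes of protein folding and of ribosome assembly rose, while neither list was called with an estimated correlation (adjusted p = 0.76 for both). Of 18 measured chaperone and heat shock genes 7 rose (8 adjusted over the list alone) and 0 fell, among them Hspa8, the constitutive cytosolic chaperone (7.53-fold, log2 difference 2.91 ± 0.52 SE, n = 4 per stage), Hsph1 (6.71-fold), the prefoldin subunit Pfdn2 (6.66-fold) and Hspa5, the chaperone of the endoplasmic reticulum (4.89-fold for probe 15330). Of 11 ribosome biogenesis genes 5 rose (8 adjusted over the list alone), including the nucleolar genes Nop58 (3.52-fold), Ncl (3.35-fold), Gnl3 (2.55-fold) and Nop2 (2.31-fold). Rab1a, a GTPase of traffic from the endoplasmic reticulum to the Golgi, rose 11.2-fold, the replication licensing factor Cdt1 8.26-fold, the splicing gene Luc7l 8.55-fold, the ribosomal protein gene Rpl12 8.36-fold and the ferritin light chain gene Ftl1 7.47-fold, with 1 of 4 2-cell arrays at the lower limit. Rgs2, a regulator of G protein signalling, fell 20.6-fold (-4.37 ± 0.38, adjusted p = 1e-07), and Tpra1, the cytochrome P450 gene Cyp2a5, Paqr3 and the spectrin gene Sptbn1 fell 7.65-fold, 7.53-fold, 6.45-fold and 4.14-fold.

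By limma 3075 probes differed between 2-cell and 4-cell embryos, 2162 higher and 913 lower in 4-cell embryos. In the blocked fit 4154 differed, and within the first batch, which holds all 8 arrays, 2967. The 2 lists were called by camera at the preset correlation (adjusted p = 0.0012 for both), with adjusted p = 0.0010 for ribosome biogenesis and 0.0015 for chaperones in the blocked fit and 0.0018 and 0.0027 within the batch. Without 2-cell array 2 or 4-cell array 4 the count was 1999 and 1951, without 2-cell array 4 it was 4618, and in a fit of the 8 arrays alone 1341.

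Between 4-cell and 8-cell embryos, which share no batch, 7 of the 8 largest named falls and 0 of the 8 largest named rises stayed past the threshold with the batch as a block, a contrast that was not tested. Il1r1, the interleukin receptor gene, was 35.2-fold lower in 8-cell embryos (log2 difference -5.14 ± 0.39 SE, n = 4 per stage) and differed by -4.53 with the block (adjusted p = 2.6e-05). Dennd11 differed by -4.54 and by -3.49 with the block, Cdc42se2, an effector of the GTPase Cdc42, by -3.98 and -3.07, Dido1 by -3.61 and -2.89, the zinc finger gene Zkscan1 by -3.50 and -2.21, the nuclear export cofactor Ranbp3 by -3.50 and -2.45, and Hspa5 (probe 5034) by -3.81 and -2.49, all past the threshold in both fits, while Zdhhc5 differed by -3.75 and by -1.61 with the block (adjusted p = 0.078). Of the rises, Ly6e differed by 4.09 and by 0.13 with the block (adjusted p = 0.96), the transcription elongation gene Supt6 by 4.09 and 0.58 (adjusted p = 0.48), the mitochondrial phosphate carrier Slc25a3 by 3.66 and 1.05 (adjusted p = 0.50) and Wbp2 by 3.73 and 1.36 (adjusted p = 0.077).

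Of 11 ribosome biogenesis genes 8 were lower in 8-cell embryos (8 adjusted over the list alone), including Imp4 (9.47-fold), Nop14 (4.66-fold), Nob1 (3.76-fold) and Ncl (3.68-fold), and with the block 0 members passed. Imp4 went from -3.24 to -1.08 (adjusted p = 0.23), Nop14 from -2.22 to -0.53 (adjusted p = 0.80) and Ncl from -1.88 to -1.15 (adjusted p = 0.24), while Nob1 kept -1.58 ± 0.44 (SE) of -1.91 ± 0.30 (adjusted p = 0.052). Camera called the list lower (adjusted p = 0.026, and 0.021 with the block), but not with an estimated correlation (adjusted p = 0.76). Among the sentinel genes, the pluripotency gene Nanog was 1.97-fold higher and Dppa3, a maternal factor, 3.18-fold lower in 8-cell embryos, and with the block they differed by 0.65 (adjusted p = 0.49) and -0.42 (adjusted p = 0.71). Dnmt3b probe 1848 was higher in both fits (1.08, adjusted p = 0.0045, and 1.74, adjusted p = 0.011), its probe 5728 only without the block (1.41, adjusted p = 0.040, and -0.14, adjusted p = 0.98), and the adhesion gene Cdh1 only with it (0.68, adjusted p = 0.072, and 1.51, adjusted p = 0.026). Of the 2 Gata4 probes, 13134 was 3.25-fold lower and 5300 differed by -0.09 (adjusted p = 0.86), and with the block probe 13134 was at -1.17 (adjusted p = 0.42).

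By limma 9285 probes differed between 4-cell and 8-cell embryos, 4726 higher and 4559 lower. With the batch as a block 578 differed, 138 higher and 440 lower, and 536 of them were among the 9285 in the same direction, 5.77%. No within-batch value exists, since each stage lies in a batch of its own, but morula arrays 1 and 2 could be set against the 4 4-cell arrays inside the first batch, in a comparison added after the data were seen. There 1171 probes differed, 449 higher and 722 lower in morulae, with Il1r1 at -4.11, Dennd11 at -3.80 and Cdc42se2 at -3.29 (adjusted p = 0.00076, 0.00083 and 6.1e-06).

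From the 8-cell embryo to the morula, 0 of the 8 largest named rises and 0 of the 8 largest named falls stayed past the threshold with the batch as a block or within a batch. In the fit without the block the ribosomal protein gene Rps23 was 6.15-fold higher in morulae (log2 difference 2.62 ± 0.55 SE, n = 4 per stage, adjusted p = 0.019), the splicing genes Srrm2 and Sf3b2 5.84-fold and 4.47-fold, the translation initiation gene Eif3a 5.77-fold and the cohesin gene Smc1a 3.94-fold, while the tubulin gene Tubb4b was 3.12-fold lower. Of 11 ribosome biogenesis genes 4 were higher (8 adjusted over the list alone): Imp4 3.36-fold, Ncl 3.03-fold, Nop56 2.75-fold and Nop58 2.24-fold.

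This comparison crossed the batch, with morulae in both and 8-cell embryos in the second. By limma 1101 probes differed, 731 higher and 370 lower in morulae, and with each array also scaled to 1 interquartile range the split was 622 and 114. With the batch as a block 0 probes differed by limma (1601 at an unadjusted p under 0.05), and within the second batch, 2 morula arrays against 4 8-cell arrays, 1 differed (3848 at an unadjusted p under 0.05). Rps23 kept a difference of 2.37 with the block (adjusted p = 0.32) and Smc1a one of 1.54 (adjusted p = 0.12). The ribosome biogenesis list was called higher by camera in all 3 fits (adjusted p = 0.0012, 0.00018 with the block and 0.0032 within the batch), with 0 members past the threshold in the last 2, and was not called with an estimated correlation (adjusted p = 0.76). Without morula 3 or 4 the pooled count was 4252 and 3105, without 8-cell array 3 or 4 it was 7 and 44, and without morula 1 or 2 or 8-cell array 2, or in a fit of the 8 arrays alone, it was 0, against 6271 at an unadjusted p under 0.05 in the fit of all arrays.

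Blastocysts were compared with morulae to see which transcripts change with the formation of the blastocoel and its epithelium. Myof, a membrane repair gene, was 7.61-fold higher in blastocysts (log2 difference 2.93 ± 0.56 SE, n = 4 per stage), although 2 of the 4 morula arrays lay at the lower limit. The pyrophosphate transporter Ank was 5.29-fold higher, the paraoxonase Pon2 4.95-fold, the tubulin Tubb5 4.37-fold, the choline transporter Slc44a1 4.32-fold, the prostacyclin synthase Ptgis 4.29-fold and the glutathione transferase Gsta4 4.01-fold. Tfrc, the transferrin receptor, fell 6.49-fold (-2.70 ± 0.34, adjusted p = 4.2e-05) and the nucleolar gene Nolc1 4.25-fold. Tspan4, Ccdc192, the lysosomal membrane gene Lamp2 and Cdkn1a were 5.47-fold, 3.79-fold, 3.37-fold and 2.42-fold lower.

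By limma 300 probes differed between morulae and blastocysts, 184 higher and 116 lower, and after quantile normalization the split was 292 and 281. In the blocked fit 289 differed (249 higher, 40 lower, 172 among the 300), and within the second batch 533 (413 higher, 120 lower, 205 among the 300). Myof differed by 3.20 and 3.06 in those fits, Ptgis by 2.50 and 2.36 and Tfrc by -2.51 and -2.33, all past the threshold. Of the 8 largest named rises 7 passed with the block and 8 within the batch, and of the 8 largest named falls 3 and 8. Tspan4, Ccdc192, Lamp2 and Cdkn1a passed within the batch and not with the block (adjusted p = 0.11, 0.16, 0.14 and 0.17), although Lamp2 kept -1.59 ± 0.48 (SE) of -1.75 ± 0.43 and Cdkn1a -1.11 ± 0.35 of -1.28 ± 0.31. Tspan4 went from -2.45 ± 0.52 to -1.81 ± 0.53 and Ccdc192 from -1.92 ± 0.43 to -1.36 ± 0.42. Of 11 ribosome biogenesis genes 0 passed the threshold over all probes and 4 were lower adjusted over the list alone. Camera called the list lower (adjusted p = 0.0012, 0.015 with the block and 0.012 within the batch), and not with an estimated correlation (adjusted p = 0.76). Without morula 1 or 2 or blastocyst 1, 2 or 3 the count was 138, 155, 154, 174 and 159, and without morula 3 it was 981.

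Inside the second batch blastocysts could be set against 8-cell embryos directly, again in a comparison added after the data were seen. There 3786 probes differed, 2424 higher and 1362 lower in blastocysts, with Rps23 higher by 4.64 ± 0.32 (SE, n = 4 per stage), Pon2 by 3.63 ± 0.18, Ptgis by 3.36 ± 0.20 and the scaffold gene Iqgap1 by 3.26 ± 0.34, genes picked after their values were seen. Ccdc192 fell by 2.77, Tfrc by 2.44 and Tspan4 by 2.30 on the log2 scale.

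The untreated controls of the treatment set followed the first and second cell cycles in separate arrays. From 21 to 32 h, within the 1-cell stage, Lipa, the lysosomal acid lipase, rose 7.25-fold (log2 difference 2.86 ± 0.53 SE, n = 3 per group), Nusap1 5.29-fold and the kinase gene Cdk11b 2.61-fold. Slmap fell 5.09-fold (-2.35 ± 0.40), the claudin gene Cldn13 5.63-fold, Saraf 3.54-fold, the cadherin family gene Fat1 3.50-fold and Ptprf 3.21-fold. Immediate early genes as a list were called lower (adjusted p = 0.021, and p = 0.60 with an estimated correlation), with 0 of 6 members past the threshold and 1 lower adjusted over the list alone.

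By limma 71 probes differed from 21 to 32 h, 41 higher and 30 lower, and with each array centred on its median 13 and 16. The splits were 5 and 9 as deposited and, also scaled to 1 interquartile range, 35 and 41. Of the 30 lower probes, 15 were also among the 100 lower in fertilized than in unfertilized eggs, where independent lists would share 0.133. The shared named genes were Slmap, Saraf, Ptprf, Fat1, Lamb1, Gatm and 4930588J15Rik. Of the higher probes 3 were shared against 0.133 for independent lists, 1 of them Nusap1, and 0 probes moved in opposite directions. Without 21 h control 3 the count was 166, and without 21 h control 4 or 32 h control 1, 2 or 3 it was 8, 41, 16 and 27. In a fit of the 6 arrays alone limma called 0 probes, against 1918 at an unadjusted p under 0.05 in the fit of all arrays.

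From 32 to 43 h, across the first cleavage, genes of mitosis fell together. Of 16 measured mitosis genes 10 fell (10 adjusted over the list alone) and 0 rose, among them Cenpe, a kinetochore motor (8.79-fold for probe 8384, log2 difference -3.14 ± 0.56 SE, n = 3 per group), Cdc20, an activator of the anaphase-promoting complex (6.25-fold), the kinase Aurka (4.50-fold) and the spindle gene Tpx2 (3.66-fold). Nusap1, Prc1 and Aspm, which also act at the spindle, fell 7.84-fold, 7.10-fold and 9.69-fold. Rgs2 fell 15.2-fold, the mismatch repair gene Msh6 11.2-fold and the chaperone Hsp90aa1 11.1-fold. Of 18 chaperone genes 5 fell (7 fell and 2 rose adjusted over the list alone), Dnaja1 7.03-fold, Dnajc7 3.85-fold and Hspa4 2.45-fold. Of 6 immediate early genes 2 rose (2 adjusted over the list alone), Ier5 3.28-fold and Ier2 2.90-fold, the latter at the lower limit in 2 of 3 arrays at 32 h. Lamp2, Clcn7 and the reticulon Rtn4 rose 3.93-fold, 4.01-fold and 6.50-fold. Dnmt1 fell 3.56-fold and 3.01-fold by probes 4902 and 17956, and probe 15678 differed by -0.18 (adjusted p = 0.89).

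By limma 813 probes differed from 32 to 43 h, 90 higher and 723 lower. The mitosis list was called lower by camera (adjusted p = 5.1e-10) and also with an estimated correlation (adjusted p = 0.043). The calls of chaperones (adjusted p = 0.0098) and immediate early genes (adjusted p = 0.024) did not hold there (adjusted p = 0.42 and 0.62). Without 32 h control 2 or 3 or 43 h control 1 or 2 the count was 392, 525, 517 and 521.

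From 43 to 54 h, within the 2-cell stage, Meg3, an imprinted noncoding RNA, rose 6.68-fold (log2 difference 2.74 ± 0.57 SE, n = 3 per group, with 1 array at 43 h listed at exactly 0). The general transcription factor gene Taf7l rose 4.45-fold, the fatty acid elongase Elovl6 4.39-fold, Tfrc 4.27-fold, Nolc1 4.22-fold, Clcn7 4.19-fold and Cdkn1a 2.41-fold. Cyp2a5 fell 13.5-fold (-3.75 ± 0.71), the troponin gene Tnni3 9.12-fold, Opa1, which acts in mitochondrial fusion, 8.28-fold, the heterochromatin gene Cbx1 6.82-fold and the RNA-editing gene Adar 6.67-fold. Btg4, at the limit in all 3 arrays at 43 h, was at least 1.38-fold lower (adjusted p = 0.037). Of 11 ribosome biogenesis genes 0 passed over all probes and 6 rose adjusted over the list alone, and camera called the list higher (adjusted p = 0.019, and p = 0.60 with an estimated correlation). By limma 922 probes differed, 521 higher and 401 lower, and as deposited 475 and 184. Without 43 h control 1 or 3 or 54 h control 1, 2 or 3 the count was 468, 252, 577, 234 and 324, and in a fit of the 6 arrays alone 1684.

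Transcripts that changed between the fertilized egg and the 2-cell embryo in the stage set were followed in these controls. From 21 to 32 h their medians lay the opposite way, at 0.40 for the depleted probes (21.2% below 0, 5 rose and 7 fell past the threshold) and at -0.11 for the activated probes (62.9% below 0, 3 rose and 2 fell). At 21 h, control array 1 correlated at 0.839 and 0.896 with arrays 3 and 4, which correlated at 0.956 with each other. Whether these medians rest on array 1 was not tested. Of the 2353 2-cell-depleted probes, 360 fell and 0 rose from 32 to 43 h, and 292 fell and 6 rose from 43 to 54 h. Of the 2197 2-cell-activated probes, 32 rose and 20 fell from 32 to 43 h, and 189 rose and 0 fell from 43 to 54 h. With an estimated correlation camera called neither set in any of the 3 steps. The adjusted p from 21 to 32 h was 0.57 for the depleted and 0.83 for the activated probes, and the lowest in the later steps was 0.43. Sf3b1, Hif1a and Ezh2 were among the probes that fell in both the stage step and the 32 to 43 h step, and Ctsl, Clcn7 and Wipi2 among those that rose in the stage step and from 43 to 54 h, these 6 being picked from the overlaps after their values were seen. The signs of the medians of the 3 steps did not depend on which of the 4 scalings was used. Across probes the stage difference correlated with the control difference from 21 to 43 h at a Pearson r of 0.263 and a Spearman rho of 0.154, and with that from 21 to 54 h at 0.591 and 0.504. Of the 6183 probes called in the stage set, 62.8% moved the same way from 21 to 43 h and 86.2% from 21 to 54 h. Probes are not independent replicates, and r to 43 h was 0.438 without 21 h control 1 and 0.055 without 21 h control 3.

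**Figure D3:**
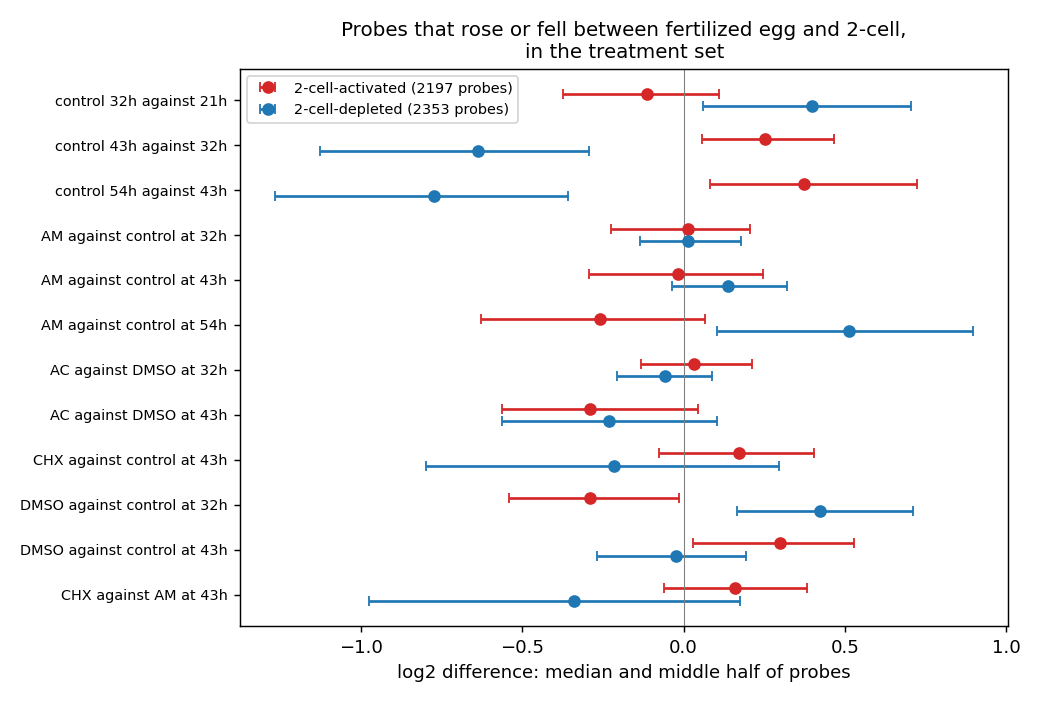
Median log2 difference (x axis), with the middle 50% of probes as bars, of 2-cell-activated (red) and 2-cell-depleted probes (blue) in each comparison of the treatment set (y axis). With AM at 54 h the activated probes have a median of -0.26 and the depleted probes of 0.51, opposite in sign to the controls from 43 to 54 h (0.37 and -0.77), a comparison that shares the 54 h control arrays. Those arrays enter the 2 comparisons with opposite signs, which favours opposite medians.

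AM, read here as α-amanitin, was taken to ask which RNAs depend on the embryo's own transcription. At 54 h, Zfp42, a marker of pluripotent cells, was 37.4-fold lower with AM than in controls (log2 difference -5.22 ± 0.85 SE, n = 3 per group, adjusted p = 0.00023). Castor1, an arginine sensor, was 13.2-fold lower, Sbno1 12.3-fold, Taf7l 12.1-fold, Brf2, a factor of RNA polymerase III, 11.9-fold, Meg3 11.8-fold, Ccdc192 11.1-fold and Cdkn1a 2.12-fold. Transcripts that were higher with AM included Cmss1 (5.06-fold), the SUMO ligase Pias2 (4.60-fold), the actin regulator Abi1 (3.94-fold) and the ubiquitin ligase Trip12 (3.89-fold). Eif1ax, a translation initiation factor, was 2.23-fold higher by probe 11690 and differed by 0.59 by probe 18930 (adjusted p = 0.46). Btg4 was 1.35-fold higher with AM (adjusted p = 0.039), with 2 AM arrays and 1 control array at the limit, and its difference was -0.19 centred, -0.17 as deposited and -0.48 scaled to 1 interquartile range.

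Of the 2197 2-cell-activated probes, 289 were lower and 4 higher with AM at 54 h, with a median difference of -0.26, and of the 2353 depleted probes 189 were higher and 31 lower, with a median of 0.51. Without a fold minimum, 346 probes were both higher at the 2-cell stage and lower with AM, where independent lists would share 142, and 214 were both lower at the 2-cell stage and higher with AM, against 61.6. Ctsl, Ankrd10, Wipi2, Clcn7, Hsph1, Nolc1 and Tfrc belonged to the former and Opa1 and Hif1a to the latter, all picked from the overlaps after their values were seen. With camera and an estimated correlation neither set was called (adjusted p = 0.43 and 0.57). The 289 was 174 without 54 h control 2, and the 189 was 89, 96, 109 and 92 without 54 h control 2 or 3 or AM array 2 or 3.

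By limma 1457 probes differed with AM at 54 h, 478 higher and 979 lower, with a split of 218 and 880 where each array was centred on its median and of 166 and 758 as deposited. Without 54 h control 2 or 3 or AM array 3 the count was 783, 906 and 949, and in a fit of the 6 arrays alone 652. At 32 h limma called 0 probes with AM (475 at an unadjusted p under 0.05), and at 43 h 0 (982), with 22 without AM array 1 and 2 without 43 h control 3. Both unadjusted counts lie below the share of 0.05 of all probes that would pass if none differed. Mitosis genes as a list were called higher with AM at 43 h (adjusted p = 0.023, and p = 0.63 with an estimated correlation), with 0 of 16 members past the threshold, adjusted over the list alone as well. The AM effect at 54 h correlated across probes with that at 43 h at r = 0.295, and 81.9% of the 1457 probes differed in the same direction at 43 h. That share was 82.8% for AC against DMSO and 70.5% for CHX against control at 43 h, so it was not particular to AM. The difference between the AM effects at 54 and 43 h passed for 18 probes, all lower at 54 h. The named ones were Hspb1, a small heat shock gene (-3.12 ± 0.50 SE), and Meg3 (probe 2972, -2.67 ± 0.50). The difference between the AM effects at 43 and 32 h passed for 0 by limma (302 at an unadjusted p under 0.05). The 18 became 4, 74 and 2 without 43 h control 1, 2 or 3, 45, 2 and 5 without 54 h control 1, 2 or 3, 3 and 5 without 43 h AM array 1 or 2 and 59 and 4 without 54 h AM array 1 or 3, and 4 centred or as deposited.

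AC, read here as aphidicolin and set against DMSO, was taken to address dependence on DNA replication. At 43 h Klhl24, an adapter of ubiquitin ligases, was 3.36-fold higher with AC (log2 difference 1.75 ± 0.26 SE, n = 3 per group), the RNA-binding gene Sltm 2.29-fold and Rnf13, a ubiquitin ligase, 2.27-fold. Pdcd11, which acts in ribosomal RNA processing, was 4.98-fold lower, with 1 AC array at the lower limit, Clcn7 4.88-fold, the aldolase Aldoc 2.73-fold and Ankrd10 2.63-fold. Of 14 primitive endoderm and basement membrane genes 0 passed over all probes and 3 were higher adjusted over the list alone, and the list was called higher (adjusted p = 0.019, and p = 0.60 with an estimated correlation).

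By limma 46 probes differed with AC at 43 h, 30 higher and 16 lower, and with each array centred on its median or as deposited 1 and 1. Also scaled to 1 interquartile range, the split was reversed at 5 and 19. Without AC array 1 the count was 2866, 1287 higher and 1579 lower, and without AC array 2 or 3 or DMSO array 1 or 3 it was 4, 30, 11 and 15. With untreated controls in place of DMSO 38 probes differed (18 higher, 20 lower), and none of the 7 genes named above was past the threshold, Klhl24 differing by 0.29 and Clcn7 by -0.58. In a fit of the 6 arrays alone limma called 0, against 2844 at an unadjusted p under 0.05 in the fit of all arrays. The 3 AC arrays at 43 h had the lowest mean correlations with their group within the treatment set, 0.760, 0.797 and 0.852. At 32 h limma called 0 probes with AC (424 at an unadjusted p under 0.05, below the share of 0.05 that would pass if none differed). The AC effect did not differ detectably between 43 and 32 h, with 0 probes past the threshold (1324 at an unadjusted p under 0.05) and 128 without AC array 1 of 43 h. The AC effect and the AM effect at 43 h differed at 1 probe, number 7831, unnamed here and picked because it alone passed (2.00 ± 0.32 SE, adjusted p = 0.032; 1880 at an unadjusted p under 0.05), with 280 without AC array 1 and 10 without AC array 3. The count was 1 without 43 h control 2 or DMSO array 3 and 0 without any other array of the 4 groups, and was 0 centred or as deposited and 10 (1 higher, 9 lower) also scaled to 1 interquartile range.

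CHX, read here as cycloheximide, was compared with the control at 43 h. Of 16 mitosis genes 7 were higher with CHX (8 adjusted over the list alone) and 0 lower, and the list was called higher (adjusted p = 1.7e-07), but not with an estimated correlation (adjusted p = 0.10). Among the 7 were Cenpe (5.72-fold and 5.39-fold by 2 probes), Cdc20 (5.12-fold), the mitotic kinesin Kif20a (5.11-fold, log2 difference 2.35 ± 0.30 SE, n = 3 per group) and Aurka (3.03-fold). Msh6 was 7.22-fold higher, Zfp692 4.17-fold, Dnaja1 3.62-fold and Lamb1 3.59-fold. Zfp42 was 9.18-fold lower with CHX (-3.20 ± 0.85, adjusted p = 0.041), the GTPase activator Arhgap29 7.97-fold, Insc, which acts in spindle orientation, 7.73-fold, the ribosomal protein gene Rps13 7.27-fold, the growth factor gene Tgfb2 7.23-fold and Scel 6.48-fold.

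By limma 508 probes differed with CHX, 224 higher and 284 lower, with 228 and 182 as deposited. Without 43 h control 1 or 2 or CHX array 2 or 3 the count was 240, 169, 219 and 250, in a fit of the 6 arrays alone 55, and against DMSO in place of the control 955. Set against AM at the same hour, CHX embryos had 349 probes that differed, 101 higher and 248 lower, with Msh6, Kif20a, Cdc20 and Lamb1 higher by 6.31-fold, 3.88-fold, 3.66-fold and 3.48-fold and Insc, Arhgap29, Rps13 and Tgfb2 lower by 8.93-fold, 8.50-fold, 7.82-fold and 6.29-fold. Of 16 mitosis genes 3 were higher (6 adjusted over the list alone; adjusted p = 0.00042 for the list, and p = 0.42 with an estimated correlation). Without AM array 1, 2 or 3 or CHX array 2, 3 or 4 the count was 144, 84, 184, 196, 150 and 231, and in a fit of the 6 arrays alone 47.

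DMSO alone was compared with untreated controls. At 32 h the leucine-rich repeat gene Lrr1 was 3.03-fold higher (log2 difference 1.60 ± 0.30 SE, n = 3 per group), Timeless, which acts at replication forks, 2.90-fold and the deubiquitinase Usp48 2.20-fold. Mindy3 was 6.19-fold lower, the ubiquitin ligase subunit Btrc 5.47-fold, the mitochondrial import receptor Tomm70a 4.22-fold and the kinase Vrk1 3.29-fold, and Tmtc3 differed by -2.43 on the log2 scale. Mitosis genes as a list were called higher (adjusted p = 0.025, and p = 0.66 with an estimated correlation), with 0 of 16 members past the threshold and 3 higher adjusted over the list alone. By limma 148 probes differed at 32 h, 31 higher and 117 lower, with 2 and 52 where each array was centred and 1 and 42 as deposited. At 43 h limma called 0 (1655 at an unadjusted p under 0.05), with 2, 1 and 4 without 43 h control 2 or DMSO array 2 or 3. Of the 148 probes 97.3% differed in the same direction at 43 h, in arrays not shared between the hours. Without 32 h control 1 or 2 or DMSO array 1 or 2 the count at 32 h was 66, 91, 80 and 72, and in a fit of the 6 arrays alone 36.

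Of the 15 list calls above, each kept the sign of its members' median difference as deposited, centred, quantile-normalized and scaled to 1 interquartile range. The remaining 17 gene lists were called in no comparison of either set. Their lowest adjusted p over all comparisons was 0.23 for oocyte genes, 0.34 for maternal mRNA storage and decay, 0.18 for 2-cell embryo genes, 0.13 for ribosomal proteins, 0.15 for translation factors, 0.51 for RNA polymerase II and its general factors and 0.24 for splicing factors. It was 0.64 for the proteasome, 0.15 for oxidative phosphorylation, 0.32 for glycolysis, 0.24 for DNA replication, 0.63 for chromatin and DNA methylation and 0.25 for pluripotency and inner cell mass genes. For trophectoderm it was 0.13, for epithelial junction and fluid transport genes 0.52, for imprinted genes 0.45 and for cumulus and granulosa cell markers 0.13.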

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

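The score of the arrays on the axis between unfertilized eggs, the comparison of AC array 1 with the means of other groups, the number of false calls set against the calls kept with the batch as a block, the fits with the array batch, and the comparison of blastocysts with 8-cell embryos inside 1 batch were chosen only after the result was seen.

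Among 35 measures of single arrays in groups of 4, 3 lay far from the rest of their group, where chance picks about 1 in 20 groups. Unfertilized egg 4 had 0.66% of its values at a limit against 1.48% to 1.56% in eggs 1 to 3, and morula 3 had 0.412% against 1.43% to 1.48% in the other morulae. Fertilized egg 2 had a mean correlation of 0.850 with the others of its group, which had 0.905 to 0.915. Among 176 sets of 4 values of named genes, 6 held such a value, fewer than chance picks at that rate. The methyltransferase gene Dnmt3b lay at -0.59 in 2-cell array 1 against 0.46 to 0.57, Cdc42se2 at -4.23 in 8-cell array 3 against -3.70 to -3.60, and Slc25a3 at 2.74 in 8-cell array 4 against 3.83 to 3.94. In morula 3, Rps23 lay at -1.51 against -0.50 to -0.40, Smc1a at -1.35 against -0.32 to -0.19 and Eif3a at -0.84 against 1.24 to 1.31.

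The AM effect at 54 h differed from that at 43 h for 18 probes, and the AC effect from the AM effect at 43 h for 1, by a test of the difference between the effects.

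The first pattern weighed is that 8-cell and blastocyst arrays differed from 4-cell arrays in the probes that part egg 4 from eggs 1 to 3. Whether an array batch, which no label records, is the source of it was not decided, because the score on that egg axis, 0.5725 at its lowest in 8-cell and blastocyst arrays, is the pattern itself. That a batch shift of equal size at all stages accounts for every call between 8-cell and 4-cell embryos was argued against. With the batch as a block 5.77% of the calls passed, 536 probes with Il1r1 among them (4.16% to 5.93% with each of 15 arrays left out). The false calls expected at the threshold were 0.311%, a measure that replaced a bound of 5% which that range straddled. A shift that differs between stages was not argued against, because the block takes out 1 shift per probe. The morula split followed the egg split with a slope of 0.503 and a correlation of 0.601 across probes, so an equal shift was not shown. The change of stage, which the design names, cannot be told apart from the batch for the calls that ended, because no batch holds both stages and only unfertilized eggs and morulae link the batches. With the block the difference of Ly6e went from 4.09 to 0.13, so that call ended with the size of the difference, while that of Rps23 from 8-cell embryo to morula kept 2.37 of 2.62 and ended with its adjusted p at 0.32.

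The second pattern is that AM changed 0 probes at 43 h by limma (982 at an unadjusted p under 0.05) and 1457 at 54 h. Tested directly, the AM effects at 54 and 43 h differed for 18 probes, and 13 of 100 splits of the arrays were as large. The difference between the hours that is weighed here was therefore itself not established. A wider spread between arrays at 43 h was argued against, since the median SD within groups at 43 h was 0.948 of that at 54 h. A later onset, in which the transcripts that AM lowers at 54 h are not yet made at 43 h, may contribute but was not decided: over the 289 activated probes lowered at 54 h, the median difference with AM at 43 h (-0.38, below 0 in 83.4%) was 0.230 of that at 54 h (-1.67), between the bounds set for and against it, with a choice of probes that favours a larger median at 54 h. In controls these probes were at a median of 0.41 from 32 to 43 h (below 0 in 24.2%) and of 1.15 from 43 to 54 h, so that most lay higher by 43 h already. That goes against none of them being made by then, but it shares the 43 h control arrays with the AM difference at 43 h. Over all 2197 activated probes the median from 32 to 43 h was 0.25 (below 0 in 20.7%), so the rise was not particular to these 289. A lower reach of the inhibitor at 43 h stays open, as untested.

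The third pattern is the low count of 46 probes with AC at 43 h, whose arrays correlated weakly with each other. Array 1 may hide changes there, since 2866 probes passed without it, against 4 and 30 without AC array 2 or 3. A difference in spread between the arrays was not decided. Their mean correlation of 0.803 after scaling to 1 interquartile range cannot change with the scaling. In a look added later, the deposited interquartile ranges of the 36 treatment arrays followed their main axis of variation within groups. That correlation was 0.667 (p = 0.016 by permutation within groups), and 0.455 without the 2 farthest arrays. Of the AC arrays at 43 h, array 1 had a range of 1.52 against 2.60 and 2.15, and lay on the other side of that axis. Whether spread was the cause cannot be told from this. That array 1 could be an array of another group met the bound set for it and was still not decided. Its correlation was 0.788 with the mean of the other 43 h AC arrays and 0.947 with that of 32 h AC, a difference of -0.159. It was 0.944 for 32 h controls, 0.943 for 32 h DMSO, 0.931 for 43 h controls, 0.926 for 43 h AM and 0.923 for 43 h DMSO. The same would follow if AC arrays 2 and 3, which correlated at 0.8885 with each other, were the ones apart. A different response of those embryos to AC was not tested and stays open.

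Other splits of the same arrays were used to see whether an arbitrary split of the arrays could give counts as large. Over 35 splits of 8 arrays, only the real split reached its count for 2-cell embryos against fertilized eggs (1 split as large, real count 6183, highest other 3408), 4-cell against 2-cell embryos (1, 3075, 1973), 8-cell against 4-cell embryos (1, 9285, 0), morulae against 8-cell embryos (1, 1101, 5), blastocysts against morulae (1, 300, 0), and blastocysts against 8-cell embryos inside 1 batch (1, 3786, 2). A share of 1 in 35 is the smallest that these splits can give, and it was not corrected for the number of comparisons. The splits take the array as the unit, and no label says whether the arrays of a group came from separate collections. These splits leave the batch aside: with it as a block the counts were 578 for 8-cell embryos, 0 for morulae by limma (1601 at an unadjusted p under 0.05) and 289 for blastocysts against morulae, and within 1 batch 1 and 533 for the last 2. For any change over the stages, too, only the real split reached its count (1 of 100 splits, 14515, highest other 990). Chance was not excluded for fertilized against unfertilized eggs, where 2 of 35 splits were as large (173, highest other 211), the other one setting unfertilized egg 4, of the second batch, with fertilized eggs 2 to 4. With the batch as a block that count was 374 and within 1 batch 288.

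In the treatment set, 10 splits of 3 against 3 arrays are too few for a share under 0.05. The real count and the highest other were 71 and 0 for controls from 21 to 32 h, 813 and 0 from 32 to 43 h, 922 and 0 from 43 to 54 h, 0 and 0 for AM at 32 h, 0 and 48 at 43 h, 1457 and 4 at 54 h, 0 and 1 for AC at 32 h, 508 and 0 for CHX, 148 and 0 for DMSO at 32 h, 0 and 1 at 43 h and 349 and 2 for CHX against AM. The number of splits as large was 1 for each of these with a real count above 0, and by construction 10 for those with 0. For AC at 43 h it was 4, with 46 and 2892, the latter setting AC array 1 with DMSO arrays 1 and 3, which points to a structure of the arrays. For differences between effects, chance was not excluded for AM at 54 less 43 h, where 13 of 100 splits were as large (18, highest other 1251), and AC less AM at 43 h (28, 1, 1174). For AM and AC at 43 less 32 h, with real counts of 0 and highest others of 2 and 2868, all 100 splits are as large by construction and say nothing. The high counts in other splits point to a structure of the arrays there too. Counts of 0 are by limma, and at an unadjusted p under 0.05 the counts were 475 for AM and 424 for AC at 32 h, 1655 for DMSO at 43 h, 302 for the AM difference and 1324 for the AC difference. Of these, 475, 424 and 302 lie below the share of 0.05 of all probes that would pass if none differed.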

How the results depend on the processing

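Leaving out probes at exactly 0, scaling each array to 1 interquartile range, the fits with the array batch, and leaving out arrays for the 2-cell probe sets and the correlation of the array sets were chosen only after the result was seen. With each array centred, 167 of 187 differences of named genes were counted as keeping their direction and their side of the threshold. Of the rest, 19 no longer passed and 1 changed sign. Here and below, a change of sign was counted only for differences past the threshold in the main fit. A difference not past it was counted as kept if its sign changed. The numbers that kept both, out of those that could be recomputed, were 88 of 90 after quantile normalization, 75 of 97 as deposited, 88 of 95 without the probes of lowest mean, 117 of 187 in fits of only the arrays compared, 183 of 187 with trend and robust settings, 175 of 187 with the replicate block, 184 of 184 without probes at 0, 173 of 187 scaled to 1 interquartile range, 64 of 90 with the batch as a block and 59 of 71 within 1 batch. With untreated controls in place of DMSO 0 of 7 did, and with DMSO for the 43 h control 14 of 15. Over all arrays left out in turn 1078 of 1314 did, 234 no longer passed, 2 newly passed and 0 changed sign. Btg4 with AM at 54 h changed sign: -0.19 centred, -0.17 as deposited and -0.48 scaled. No signal over background was used here, and values held at a limit, 1.47% of all, bound the differences they enter.

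Counts that moved by over 1.5 times follow, and the cause was not tested unless said. Quantile normalization gave 401 for fertilized against unfertilized eggs and 573 for blastocysts against morulae. Without the probes of lowest mean fewer probes were tested, and the counts were 62 for fertilized eggs, 1808 for 4-cell against 2-cell embryos, 128 for blastocysts, 25, 413 and 266 for the controls to 32, 43 and 54 h, 497 for AM at 54 h, 5 for AC at 43 h, 273 for CHX, 1 for DMSO at 43 h, 204 for CHX against AM and 0 for the AM effect at 54 less 43 h. Only the arrays compared, with fewer arrays for the spread, gave 0 for fertilized eggs, 3218 for 2-cell embryos, 1341 for 4-cell embryos, 0 for morulae, 0 for controls to 32 h and 1684 to 54 h, 652 for AM at 54 h, 0 for AC at 43 h, 55 for CHX, 36 for DMSO at 32 h, 47 for CHX against AM, 1 for AM at 54 less 43 h and 0 for AC less AM. Centring gave 29 and 540 for the controls to 32 and 43 h, 2 for AC at 43 h, 54 for DMSO at 32 h, 4 for AM at 54 less 43 h and 0 for AC less AM. Values as deposited gave 14 for controls to 32 h, 924 for AM at 54 h, 2 for AC at 43 h, 43 for DMSO at 32 h, 4 for AM at 54 less 43 h and 0 for AC less AM. Trend and robust settings gave 14 for AC at 43 h. Without probes at exactly 0, AC less AM had 0. Scaling to 1 interquartile range gave 605 for controls to 54 h, 24 for AC at 43 h, 4 for AM at 54 less 43 h and 10 for AC less AM. With the batch as a block the counts were 374 for fertilized eggs, 578 for 8-cell embryos, 0 for morulae and 9242 for any change, and within 1 batch 288 for fertilized eggs, 1 for morulae and 533 for blastocysts. CHX against DMSO gave 955, and AC at 32 h against untreated controls 111 (5 higher, 106 lower). A minimum of 3-fold, which makes the sets smaller, gave 168 activated probes lower and 104 depleted probes higher with AM at 54 h, and with that minimum the activated set was called lower also with an estimated correlation (adjusted p = 0.026). With an estimated correlation 1 of 15 list calls held. The correlation of the array sets was 0.591 with the 54 h control in place of that at 43 h.

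The replicate numbers were not taken to pair the arrays in the main fits, since not every same-number pair deviated together. That criterion does not exclude a technical run shared by some arrays of the same number. In the treatment set, the lowest counts of features at the upper limit all fell on arrays numbered 3. They were 5 for AC, 93 for AM and 156 for DMSO at 32 h, and 79 for AM at 54 h. Next came 298 for DMSO at 43 h and 304 for controls at 54 h, both also numbered 3. The lowest array with another number was AC array 1 at 32 h, with 317. The remaining arrays numbered 3 had 321 to 369, so the number alone did not mark a low count. Over 84 same-number pairs of the stage set the mean correlation of deviations from the group means was -0.016 (-0.435 to 0.588, 22 over 0.1), against 0.00548 for other pairs, and over 177 pairs of the treatment set 0.0725 (-0.494 to 0.569, 81 over 0.1), against -0.0309. With the replicate number as a block the counts were 109 for fertilized eggs, 27 for controls to 32 h, 326 for CHX and 216 for CHX against AM, and the other counts stayed within 1.5 times.

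Leaving out each array in turn gave counts from 13607 to 15609 for any change, 21 to 412 for fertilized eggs, 4910 to 7691 for 2-cell, 1951 to 4618 for 4-cell and 7958 to 8840 for 8-cell embryos, 0 to 4252 for morulae and 138 to 981 for blastocysts. For controls they were 8 to 166, 392 to 700 and 234 to 717 to 32, 43 and 54 h. For AM they were 0 to 0, 0 to 22 and 783 to 1879 at 32, 43 and 54 h, for AC 0 to 0 and 4 to 2866 at 32 and 43 h, for CHX 169 to 442, for DMSO 66 to 161 and 0 to 4 at 32 and 43 h and for CHX against AM 84 to 231. Differences between effects gave 0 to 0 for AM at 43 less 32 h, 2 to 74 for AM at 54 less 43 h, 0 to 128 for AC at 43 less 32 h and 0 to 280 for AC less AM. The activated probes lower with AM at 54 h numbered 174 to 335, the depleted probes higher 89 to 227, and the correlation of the array sets ran from 0.0547 to 0.438.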

Other observations

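The overlaps of calls, the enlarged look at AC without array 1 and the measure of a shared fall were chosen only after the result was seen.

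Transcripts lowered by AM at 54 h and by CHX at 43 h overlapped, in comparisons that share no array: 81 probes were lower in both, where independent lists would share 12.3. Among them were Zfp42, Lamp2, the histone chaperone gene Set and the transcription factor gene Sp3, picked after their values were seen. Of the 16 probes lower with AC at 43 h, 12 were also lower with AM at 54 h against 0.694 for independent lists, including Ankrd10, Clcn7 and Pdcd11. Across probes, which are not independent, the AM effect at 54 h correlated with the AC effect at 43 h at a Pearson r of 0.402 and with the CHX effect at 0.202.

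The 2-cell probe sets were also counted in other treatments. With CHX at 43 h, 11 of the 2197 activated probes were higher and 41 lower, while the median of the set was 0.17 (31.5% below 0). Of the 2353 depleted probes 83 were higher and 92 lower, with a median of -0.21. With DMSO at 32 h, 1 activated probe was higher and 41 lower, with a median of -0.29, and 14 depleted probes were higher and 0 lower, with a median of 0.42. At 43 h DMSO did not repeat this, the medians being 0.30 for the activated probes (22.8% below 0) and -0.02 for the depleted probes. Against AM at the same hour, 44 depleted probes were higher and 127 lower with CHX (median -0.34), and 4 activated probes higher and 8 lower (median 0.16). With an estimated correlation camera called neither set in these comparisons, the lowest adjusted p being 0.43.

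Without AC array 1 of 43 h, left out because it correlated weakly with the other AC arrays of that hour, 2866 probes differed between AC and DMSO, 1287 higher and 1579 lower. That choice favours larger counts, and whether array 1 or the other AC arrays were atypical was not decided. The chromatin remodelling gene Pbrm1 was then higher by 3.12 ± 0.45 (SE, adjusted p = 0.00045), where array 1 alone lay 0.16 above DMSO, and Zfp42 lower by -4.14 ± 0.69 (adjusted p = 0.0011), where array 1 lay 0.40 above. Of the 2-cell-depleted probes 675 were lower and 25 higher, with a median of -0.82, and of the activated probes 116 were lower and 64 higher. Primitive endoderm and basement membrane genes were called higher (adjusted p = 0.0062, and p = 0.091 with an estimated correlation).

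The probes lower in fertilized than in unfertilized eggs and those lower in controls from 21 to 32 h shared 15 members, 113 times the number for independent lists, in arrays of different sets with different references, and 0 probes moved in opposite directions. That overlap is the pattern itself, so passing the bound of 5 set for it decides nothing and no explanation of it was tested.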
